A study of Mus musculus with 6 samples.

How the data were processed

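Whole testes were taken from 3 Alkbh1 KO and 3 WT mice, and total RNA was extracted with Trizol and labelled with biotin in 1 amplification cycle, per the labels' protocols. Each mouse gave 1 Affymetrix mouse expression array. The authors deposited 1 table of normalized log2 expression values with 45101 probe sets and 6 arrays. GCOS version 1.4 is named in the submitters' processing notes. The background correction, the summary of probes into probe sets and the normalization between arrays are not given in the sources used here. The log2 scale was read from the values, which ran from 2.61 to 15.00 with array medians between 6.62 and 6.65. No centring per gene was seen. A normalization that equalises arrays would hide a change of the whole transcriptome, and log2 values near the lower end hold mostly background, where fold changes are understated. Scanner files and detection calls were not used here, so signal over background per probe set is unknown.

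Samples were grouped by the genotype in their titles. The source label gives the strain as C57/BL6, while the genotype field of the first sample spells it differently. The labels give separate mice, so that replicates are biological. The 64 control probe sets were left out, and of the other 45037 the upper 60% by mean log2 over all 6 arrays were kept (27022, lowest mean 6.02). Gene names came from the platform annotation and were updated through gene ids with a RefSeq table of assembly GRCm38.p6, which was used only for names, chromosomes and neighbours. Of the probe sets, 34945 named 1 gene, 932 several and 9160 none, and 99.4% of those naming 1 gene matched the table. No gene was named from a probe set with several genes.

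KO was compared with WT by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over the kept probe sets at a threshold of 0.05. For lists and chromosomes, each of 13897 genes was represented by its probe set with the highest mean. The 36 gene lists of testis cell types, other tissues and pathways were fixed before the data were examined, as were the tests and the rule for named genes, and lists with at least 5 measured genes (35) were tested with limma's camera at a preset correlation of 0.01. An estimated correlation and fry were run beside it. Fry tests whether the genes of a set move on balance in 1 direction and does not compare the set with other genes, while camera does, so that its direction is relative to all other genes. Chromosomes 1 to 19, X and Y and the genes within 10 Mb of Alkbh1 were tested in the same way. Figures were drawn with matplotlib 3.10.9.

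The rule for named genes took the AlkB family, then up to 12 genes with the largest rises and up to 12 with the largest falls among those that passed. Open places were filled by the smallest p among genes without overlap between groups. It then took from each list members that passed adjusted over the list alone, otherwise up to 2 with the smallest p, and up to 6 genes near Alkbh1. Of the genes taken by this rule, 1 is not reported here. Members of called lists are given, and those of lists that were not called are mostly left out of the text. Genes of the X chromosome and of crowded bins, and Rest, were named after their values were seen. Trmt5 and Meg3 met the rule as members of lists that were not called, and were picked for the text after their values were seen.

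The pipeline was tested on simulated data for 3 against 3 arrays. Over 10 runs on 27022 probe sets, 3.56% of its calls were false. It recovered 48.2% of probe sets changed by 0.5 log2, 88.7% of those changed by 1 and 99.4% of those changed by 2. Each run held more changed probe sets than the 11 called between KO and WT, which eases the adjusted threshold. Recovery on the real arrays may therefore be lower. In 50 runs on 13897 independent genes, a shift of 0.07 in the Sertoli list was called in 100% of runs and 0.242% of unshifted lists were called. Real genes are correlated, which the simulation left out, so its rate of unshifted lists called does not carry over to the real arrays. A split of the real arrays that mixed KO and WT called 9 lists. Alternatives covered the normalization, the level filter, a replicate block, the moderation of variances, array weights, the choice of probe set, the set tests and leaving out each array. Windows of 5 and 20 Mb were tried around Alkbh1.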

Results

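Alkbh1 encodes a member of the AlkB family of dioxygenases, enzymes that depend on iron and 2-oxoglutarate and that in several cases remove methyl groups from DNA or RNA. Its role in the testis was addressed by comparing whole testes of knockout mice (KO) with those of wild-type mice (WT) of the same age, 12 weeks. RNA from 3 KO and 3 WT mice was hybridised to 6 Affymetrix mouse expression arrays, 1 array per mouse, and each array gave a normalized log2 expression value for 45101 probe sets. A probe set is a group of short probes against 1 transcript region, so that a gene can have several. The number of arrays limited the precision, with a median standard error of 0.08 log2 for a KO minus WT difference. RNA integrity was high in all samples (9.8 to 10, per the labels).

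The 6 testes were alike over the transcriptome as a whole. Pearson correlations across the 27022 probe sets tested ran from 0.989 to 0.996 between arrays, within and between genotypes, where probe sets are not independent replicates. Replicates 1 and 2 of the WT group stood farthest apart (r = 0.989) and took opposite ends of the first principal component, at −24.36 and 21.03, which held 40.8% of the variance. The control RNAs spiked in before labelling had the lowest mean log2 value in WT replicate 1 (6.69) and the highest in WT replicate 2 (9.41), with the other 4 arrays between 7.59 and 8.10. The 5′ probe set for 18S ribosomal RNA read 12.16 in WT replicate 2 and from 6.63 to 8.67 in the others. The second component (22.9%) placed all 3 WT arrays below 0 and all 3 KO arrays above. For any 1 component, chance separates 3 against 3 arrays without overlap in 10% of cases. The separation by itself therefore does not show an effect of genotype.

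Alkbh1 itself fell in the KO testes. Its probe set 1434660_at read 8.60 ± 0.15 log2 in WT and 5.42 ± 0.30 in KO (mean ± SD, n = 3 each), a change of −3.18 ± 0.15 (SE) or 9.08-fold lower (limma adjusted p = 0.000582). All 3 KO values lay below all 3 WT values. The other probe set of Alkbh1, 1438681_at, read 6.99 ± 0.17 in WT and 5.97 ± 0.17 in KO, a difference of −1.02 ± 0.12 that missed the threshold (adjusted p = 0.0697). Which part of the gene was deleted is not given in the sources used here, and a probe outside the deleted part would not check the genotype. The Alkbh1 call was lost without WT replicates 1 and 2, leaving 1 WT array (−3.30, adjusted p = 0.0631, a choice made after seeing the data).

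The rest of the AlkB family did not pass the test in either direction. Alkbh6 had the smallest p among them, with a difference of −0.18 ± 0.06 (limma adjusted p = 0.908), followed by a probe set of Alkbh3, a demethylase of alkylated DNA and RNA, at 0.18 ± 0.08 (limma adjusted p = 0.967). These were the only 2 of its probe sets outside Alkbh1 at an unadjusted p under 0.05. Alkbh5 and Fto, the demethylases of N6-methyladenosine, had differences from −0.09 to 0.09 over their 4 probe sets. Alkbh2 stood at −0.10 ± 0.09, Alkbh7 at −0.01 ± 0.05 and Alkbh8, a tRNA-modifying enzyme, at 0.11 ± 0.13. The 3 probe sets of Alkbh4 lay between −0.08 and −0.03. Of the 9 family members 1 fell, Alkbh1, over all probe sets and also adjusted over the list alone. The family as a list was called lower (camera adjusted p = 0.03, median −0.054 log2). That call was lost under 14 of 20 alternatives (adjusted p from 0.0174 to 0.916 over the 20). With an estimated correlation the adjusted p was 0.916, and without Alkbh1 it was 0.629. The call was also lost without WT replicate 2 (adjusted p = 0.175), WT replicate 3 (0.0983) or KO replicate 1 (0.0872).

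**Figure D1:**
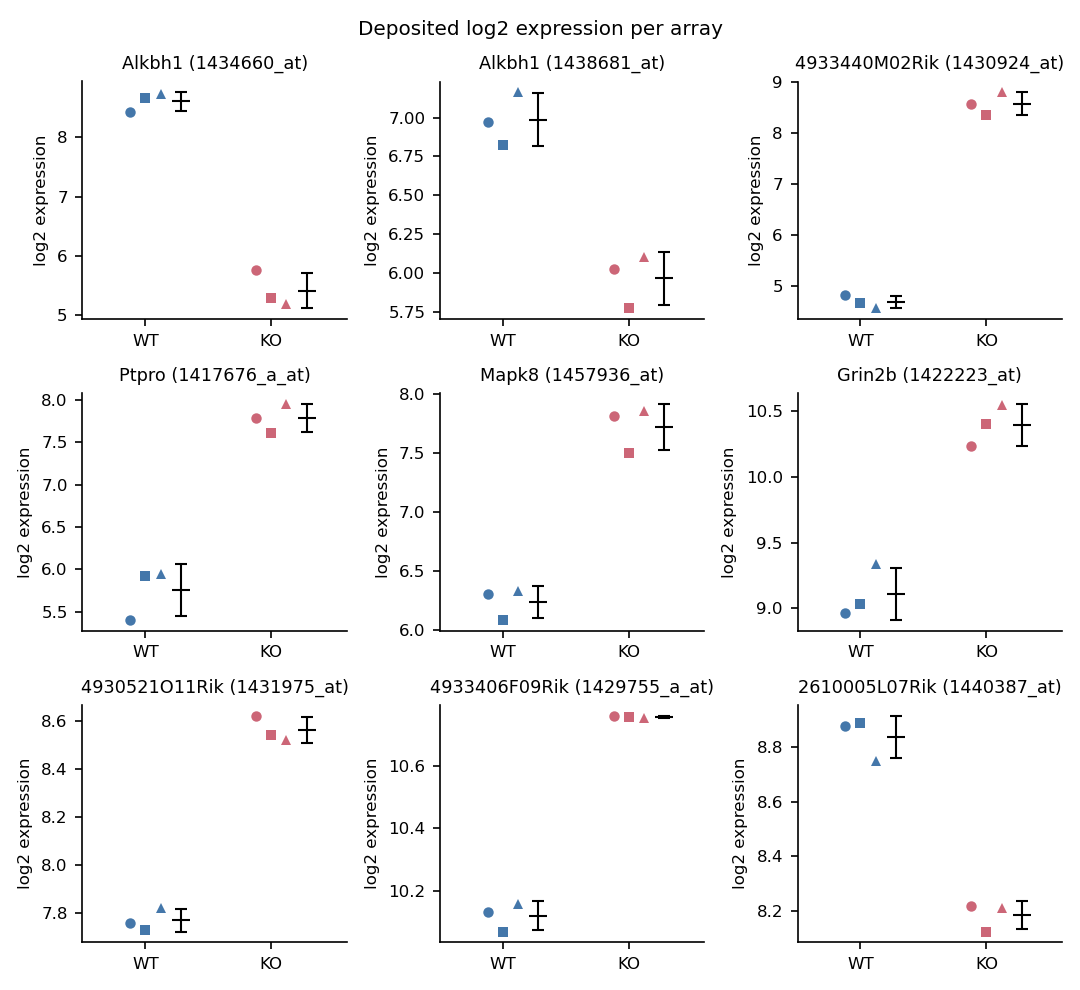
Log2 expression on each array (y axis, log2 units) for both probe sets of Alkbh1 and for the 7 other named genes that passed the test, in WT (blue) and KO (red). Circles, squares and triangles are replicates 1, 2 and 3, and black bars give the group mean ± SD. In each panel the 3 KO values do not overlap the 3 WT values, and Alkbh1 probe set 1438681_at is the only one shown that missed the threshold.

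Few transcripts changed. Of 27022 probe sets 11 changed, that of Alkbh1 included, 9 of them higher and 2 lower in KO (limma, Benjamini-Hochberg adjusted p under 0.05). They named 8 genes, of which 6 rose and 2 fell, Alkbh1 being among those that fell, and 1 changed probe set, 1429323_at, has no gene named (0.88 ± 0.05 higher in KO, adjusted p = 0.00233). The largest rise was that of 4933440M02Rik, an uncharacterised transcript on chromosome 7, from 4.69 ± 0.12 in WT to 8.58 ± 0.22 in KO, which is 14.9-fold (adjusted p = 4.61e-05). Ptpro, a receptor-type tyrosine phosphatase on chromosome 6, rose 4.09-fold (2.03 ± 0.16, adjusted p = 0.00944). Grin2b, an NMDA glutamate receptor subunit also on chromosome 6, rose by 1.29 ± 0.12 log2 from 9.11 ± 0.20 to 10.40 ± 0.16 (adjusted p = 0.0181). Its 3 other probe sets lay under the level filter, with differences of −0.17, 0.16 and 0.22. Probe set 1457936_at of Mapk8, a chromosome 14 gene that encodes the stress-activated kinase JNK1, rose by 1.48 ± 0.12 (adjusted p = 0.00944). The other 4 Mapk8 probe sets disagreed with it in size or direction, with differences of 0.46, 0.08, 0.01 and −0.14, none of which passed. The rise of 4933440M02Rik passed whichever array was left out. Ptpro and Mapk8 lost their calls without WT replicate 3 (limma adjusted p = 0.0584 and 0.082), KO replicate 1 (0.0612 for both) or KO replicate 3 (0.0566 for both), and Grin2b without WT replicate 2 (0.0676) or KO replicates 1, 2 or 3 (0.0612, 0.128 and 0.0673).

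The remaining calls fell on transcripts with clone names. On chromosome 14, 4930521O11Rik rose by 0.79 ± 0.06 (adjusted p = 0.00954), and all 3 probe sets of 4933406F09Rik rose, by 0.64, 0.74 and 0.53 (adjusted p = 0.00954, 0.0232 and 0.0232). Their neighbour Gm3411 had a difference of 0.67 ± 0.13 without passing (adjusted p = 0.413). On chromosome 8, 1 probe set of 2610005L07Rik fell by 0.66 ± 0.07 (limma adjusted p = 0.0338). Its 7 other probe sets were lower in KO, with differences from −1.0 to −0.35. Of these, 1440184_at lay under the level filter and was not tested, and the rest did not pass. The nearby name 6820431F20Rik differed by −0.65 ± 0.10 (adjusted p = 0.158). Such clone names can stand for near-identical copies that share probes, so the assignment of these signals to 1 gene is uncertain. Without WT replicate 3 or KO replicates 1, 2 or 3, the calls of 4930521O11Rik (limma adjusted p = 0.084, 0.0612, 0.0781 and 0.0566) and of the 4933406F09Rik probe set that rose by 0.64 (0.084, 0.0732, 0.111 and 0.0659) were lost. That of 2610005L07Rik was lost whichever array was left out. Its limma adjusted p was 0.0702, 0.123 and 0.153 without WT replicates 1, 2 and 3. Without KO replicates 1, 2 and 3 it was 0.141, 0.241 and 0.124. Over the 17 alternatives that gave a value, its difference ran from −0.70 to −0.57, so it changed little in size.

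Genes that missed the threshold were named by the smallest p among those whose KO and WT values did not overlap. That trait was the rule's condition, and 11% of tested probe sets had it, against 10% by chance. Among those higher in KO were Ktn1, which encodes kinectin (0.49 ± 0.07, adjusted p = 0.111), and Rbl2, a retinoblastoma-related repressor (0.45 ± 0.06, adjusted p = 0.111). Gmfb (0.34), the phosphatase gene Dusp16 (0.29) and Dera (0.47), an enzyme of deoxyribose breakdown, had adjusted p from 0.352 to 0.413, and the other tested probe sets of Gmfb stood at 0.31, 0.30 and 0.12. Among those lower in KO, 4930470P17Rik came closest to passing (−0.56 ± 0.06, adjusted p = 0.0526), followed by the gasdermin gene Gsdma (−0.70 ± 0.08, adjusted p = 0.0843). Ptprg, another receptor-type tyrosine phosphatase, stood at −0.67 at 1 probe set (limma adjusted p = 0.109, and 0.0369 without WT replicate 1) and at −0.28, −0.24 and −0.09 at its 3 others (limma adjusted p = 0.835, 0.863 and 0.993). Plekhd1os stood at −0.71, and 1700063H04Rik was at −0.66. Hif1a, the oxygen-regulated transcription factor, lies on chromosome 12 like Alkbh1. It differed by −0.60 at 1 probe set (limma adjusted p = 0.131) and by −0.16 and 0.12 at its 2 other probe sets that were tested. Wdfy4 (−0.50) and the basement membrane gene Nid2 (−0.65) had adjusted p of 0.131 and 0.158. Many of these genes share a chromosome. Ktn1, Gmfb, Ptprg, Wdfy4 and Nid2 lie on chromosome 14, and 1700063H04Rik, Dusp16 and Dera on chromosome 6. Dusp16 and Dera share a 10 Mb stretch with Ptpro and Grin2b. Plekhd1os lies on chromosome 12, while Rbl2, Gsdma and 4930470P17Rik lie on chromosomes 8, 11 and 2.

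Most transcripts differed little, with 93.2% of differences under 0.2 log2 in size. At an unadjusted p under 0.05 there were 1380 probe sets, against 1351 expected by chance, and 2961 (11%) had no overlap between the 3 KO and the 3 WT values, which chance gives for 10%. The count of 11 changed when single arrays were left out. It was 4 without WT replicate 3, 6 without KO replicate 1 and 2 without KO replicate 3 (Alkbh1 and 4933440M02Rik), and 2 without WT replicates 1 and 2 together. Without KO replicate 2 there were 5 higher and 4 lower. A test without limma's moderation called 0 probe sets, and array weights raised the count to 2114 with the default algorithm, which did not converge, and to 46 with the gene by gene algorithm.

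Sertoli cell genes were slightly lower in KO. Of the 27 measured genes of these somatic nurse cells 22 were lower and 5 higher, with a median difference of −0.071 log2 (camera with a preset correlation, adjusted p = 0.000524). The call was lost with an estimated correlation (camera adjusted p = 0.557) and with fry (adjusted p = 0.388). It was also lost without WT replicates 1 and 2, which leaves 1 WT array. Over the 20 alternatives the mean difference ran from −0.0799 to −0.0559, against −0.0644 in the main test. No single member passed over all probe sets or adjusted over the list alone (limma, 0 of 27 in both counts, 2 at an unadjusted p under 0.05). Kitl, the KIT ligand that acts on spermatogonia, differed by −0.21 ± 0.07 and Inha, which encodes the inhibin alpha subunit, by −0.12 ± 0.05. Markers of other somatic cells were not called. Adjusted p was 0.967 for Leydig cells, 0.242 for peritubular myoid cells, 0.897 for endothelium and for macrophages, and 0.689 for lymphocytes.

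Genes of the haploid germ cells were slightly higher in KO where they lie outside the sex chromosome families. Round spermatid genes were higher in 29 of 35 cases (median 0.064, adjusted p = 0.00666) and elongating spermatid genes in 32 of 39 (median 0.055, adjusted p = 0.0198). Both calls were lost with an estimated correlation (adjusted p = 0.956 for each) and with quantile normalization (adjusted p = 0.28 and 0.668), and they held under 12 and 8 of 20 alternatives. The round spermatid call was also lost without WT replicate 2 (adjusted p = 0.16) or KO replicate 1 (0.0872), and the elongating spermatid call without WT replicate 1 (0.324), WT replicate 2 (0.086), KO replicate 2 (0.131) or KO replicate 3 (0.114). The mean elongating spermatid difference of 0.042 became 0.015 without WT replicate 1 and 0.069 without WT replicate 3. Examples were the acrosomal gene Zpbp2 (0.13 ± 0.05), Pick1 (0.13 ± 0.06) and the flagellar gene Tekt4 (0.21 ± 0.07), while Spag16, which encodes an axonemal protein, stood at −0.14 ± 0.05. None passed over all probe sets or adjusted over the list alone (limma, 0 of 35 and 0 of 39, with 1 and 2 at an unadjusted p under 0.05). Per array, WT replicates 1 and 2, the arrays that stood apart, had the lowest 2 round spermatid means (−0.046 and −0.071 against the mean of all arrays), while WT replicate 3 (0.025) lay among the KO values. Without WT replicates 1 and 2, which leaves 1 WT array, the mean difference was 0.0063 for round and −0.011 for elongating spermatids. Differences also rose with signal level. Autosomal genes were placed in 4 groups at rising level, with limits taken from the levels of the X-linked genes. The median difference was −0.0001, 0.0051, 0.0055 and 0.0235. The last of these is below the list medians of 0.064 and 0.055. Its group is broad, with 5798 genes against 2267 to 2703 in the others, and was not matched to the levels of the list genes. The comparison therefore cannot show whether the level trend is too small to account for the lists. A high percentile of the log2 values was 12.41 in WT replicate 1 and 12.54 to 12.55 on the other arrays. Whether signal level accounts for the spermatid differences was not tested.

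A list of multicopy or spermatid-expressed genes of the X and Y chromosomes went the other way. Of 13 measured genes 11 were lower in KO (median −0.046, camera adjusted p = 0.0198). Among them were the perinuclear theca genes Cypt1 (−0.17 ± 0.06) and Cypt3 (−0.28 ± 0.12). Of the 13 genes, 12 were placed on X or Y and 9 of these on X, so the list overlaps the X-linked genes below. The call was lost with an estimated correlation (adjusted p = 0.916). It was also lost without WT replicate 2 (adjusted p = 0.0782), WT replicate 3 (0.127), KO replicate 1 (0.0872) or KO replicate 2 (0.0751). It held under 13 of 19 alternatives. None of the 13 passed over all probe sets or adjusted over the list alone (limma, 1 at an unadjusted p under 0.05), and probes for multicopy genes can read several copies.

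Apoptosis genes were lower in KO in 23 of 32 cases (median −0.030, adjusted p = 0.013). The call was lost with an estimated correlation (adjusted p = 0.557), and without WT replicate 1 (0.144) or KO replicate 3 (0.139). It held under 12 of 20 alternatives. The members with the smallest p have opposite functions, Birc3 as an inhibitor of apoptosis (−0.19 ± 0.07) and Bik as a promoter of it (−0.20 ± 0.07), and 0 of 32 passed over all probe sets or adjusted over the list alone (limma, 2 at an unadjusted p under 0.05).

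**Figure D2:**
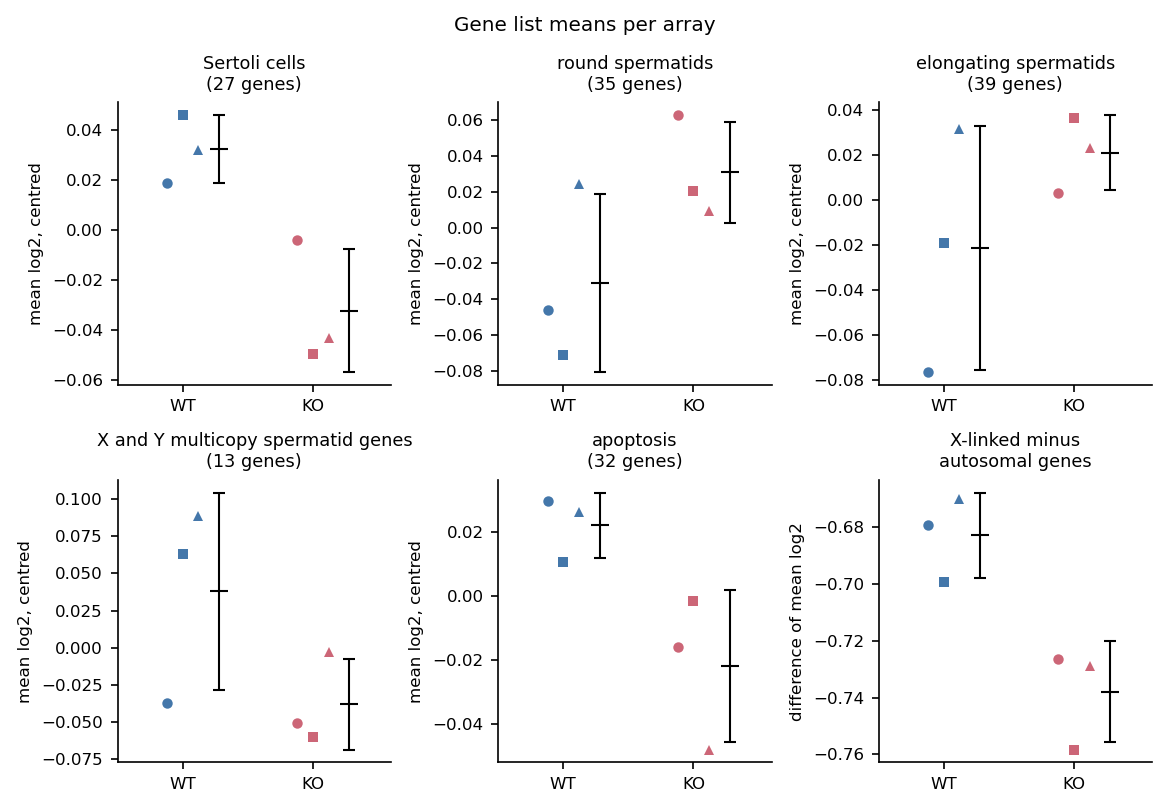
Mean log2 expression of 5 gene lists on each array, centred on the mean of all 6 arrays, and the mean of X-linked minus that of autosomal genes (y axes, log2 units), in WT (blue) and KO (red). Circles, squares and triangles are replicates 1, 2 and 3, and black bars give the group mean ± SD. KO values lie below all WT values for Sertoli cells, apoptosis and X-linked genes, and overlap them for the 3 spermatid lists.

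Earlier germ cell stages were not called, with adjusted p of 0.0836 for pachytene spermatocytes (22 of 28 genes higher in KO), 0.242 for spermatogonia and 0.949 for early meiosis. Lists close to reported activities of AlkB enzymes were not called either, at 0.629 for tRNA modification, 0.689 for base excision repair with direct reversal, 0.629 for double strand break and mismatch repair, and 0.819 for enzymes of histone and DNA methylation. For histones it was 0.689, for imprinted genes 0.689 and for the piRNA pathway 0.866. For mitochondria it was 0.629 for gene expression, 0.689 for the mitochondrial ribosome and 0.689 for oxidative phosphorylation. Stress and signalling lists stood at 0.112 for hypoxia and glycolysis, 0.629 for p53 targets, 0.629 for the integrated stress response, 0.949 for the antioxidant response, 0.689 for interferon and 0.949 for immediate early genes. Cell proliferation had 0.392, ribosomal proteins 0.629 and cholesterol synthesis 0.629. Tissue near the testis was represented by epididymis (0.274) and adipose tissue (0.629), and erythroid cells had too few measured genes (3) for a test. Of the 799 genes in these uncalled lists 0 passed over all probe sets or adjusted over the list alone (limma, 30 at an unadjusted p under 0.05). Over the 35 lists tested, camera called 6 with a preset correlation (2 without WT replicate 2 and 3 without KO replicate 1) and 0 with an estimated one (2 at an unadjusted p under 0.05), and fry called 0 (4 at an unadjusted p under 0.05). Median, mean and test did not share a sign for epididymis, immediate early genes, macrophages, endothelium, Leydig cells, the piRNA pathway, the mitochondrial ribosome and oxidative phosphorylation.

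By chromosome, the X-linked genes stood apart. Of 426 measured X-linked genes 287 (67.4%) were lower in KO, with a median difference of −0.042 log2 against 0.013 for other genes (camera with a preset correlation, adjusted p = 1.06e-06). With an estimated correlation the call was lost (adjusted p = 0.99), as it was with fry (adjusted p = 0.421). Without WT replicate 3 the mean X-linked difference of −0.0429 became −0.0278 (camera with a preset correlation, adjusted p = 0.000238). The mean of X-linked minus that of autosomal genes was −0.683 ± 0.015 in WT and −0.738 ± 0.018 in KO (SD, n = 3 each), which is 3.74% lower relative to the autosomes. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 arrays can give. No X-linked gene passed by itself (limma, 10 at an unadjusted p under 0.01). Those with the smallest p were Wdr13 (−0.31 ± 0.08), the kinase gene Cdk16 (−0.20 ± 0.05) and Rbmx (0.32 ± 0.08), which encodes an RNA-binding protein and was higher in KO. The 19 autosomes, the Y chromosome and the neighbourhood of Alkbh1 were not called. Over the 22 sets, an estimated correlation called 0 (0 at an unadjusted p under 0.05) and fry 0 (2 at an unadjusted p under 0.05).

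Near Alkbh1 on chromosome 12, no other gene passed. Within 10 Mb there were 111 measured genes, of which 0 passed, against 5 of 13694 elsewhere (limma, Fisher's exact test, two-sided p = 1). At an unadjusted p under 0.01, a threshold chosen after the data were seen, there were 7 (6.31%) against 158 (1.15%, Fisher's exact p = 0.000368). Within 5 Mb it was 4 of 74 genes (Fisher's exact p = 0.0118), and within 20 Mb 11 of 240 (Fisher's exact p = 0.000146). The antisense transcript Plekhd1os (−0.71 ± 0.10) and its partner Plekhd1 (−0.38 ± 0.09), 4930473H19Rik (−0.65 ± 0.12) and Ltbp2 (−0.43 ± 0.09), which encodes a protein of the extracellular matrix, were lower in KO. Rad51b, a homologous recombination gene, was also lower (−0.34 ± 0.09), and Tmed8 was higher (0.41 ± 0.08). Similar runs of neighbouring genes lay elsewhere. The 10 Mb bin of chromosome 6 that holds Ptpro and Grin2b had 7 of 34 genes at an unadjusted p under 0.01, and the bin of chromosome 14 with 4930521O11Rik and 4933406F09Rik had 3 of 14.

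**Figure D3:**
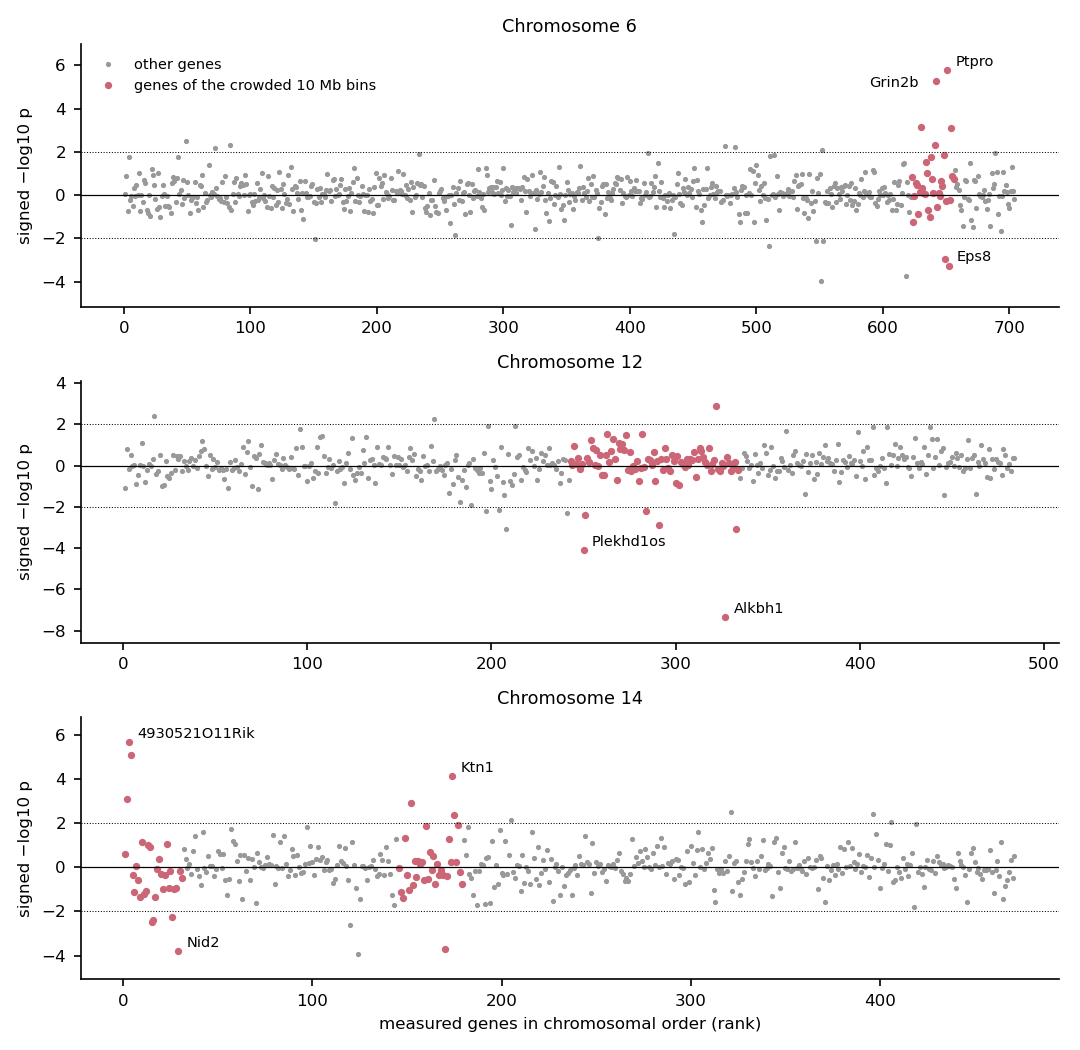
Signed −log10 of limma's unadjusted p (y axis, above 0 where KO was higher) for measured genes in their order along chromosomes 6, 12 and 14 (x axis, rank), 1 probe set per gene. Red points are genes of the 10 Mb bins with more genes under 0.01 than chance gives, grey points are the other genes, and dotted lines mark 0.01. Alkbh1 and Plekhd1os share a bin of chromosome 12, and Ptpro, Grin2b and Eps8 share 1 of chromosome 6.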

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

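The look at probe sets under the level filter was chosen only after the results were seen. Of the 18015 probe sets left out by that filter, 3 rose in KO above the level of the WT controls when all probe sets were tested with limma. Probe set 1425863_a_at of Ptpro rose by 1.49 ± 0.08 log2 (2.8-fold, from 4.53 ± 0.07 to 6.01 ± 0.06, adjusted p = 0.000499), in the direction of the Ptpro probe set above the filter.

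Probe set 1425564_at of Rest, the gene of a transcriptional repressor of neuronal genes, rose by 1.70 ± 0.13 (3.25-fold, from 5.02 ± 0.27 to 6.72 ± 0.03, adjusted p = 0.00505). Its 3 other probe sets did not pass in that fit, with differences of 0.49 ± 0.11, 0.25 ± 0.12 and 0.13 ± 0.16. Probe set 1432240_at, which has no gene named, rose by 1.54 ± 0.14 (2.91-fold, adjusted p = 0.0127).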

How the results depend on the processing

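The arrays' number and the unknown background limit what can be called, and the alternatives named here as added were chosen after seeing the data. Alkbh1 kept its direction under all 17 alternatives that gave a value, from −3.35 to −3.07, and its call under 15. The call was lost without limma's moderation (−3.18, adjusted p = 0.355) and, as an added alternative, without WT replicates 1 and 2 (−3.30, adjusted p = 0.0631; adjusted p over all alternatives from 1.94e-06 to 0.355). Its probe set was left out by the filter at the upper 40%. The 11 changed probe sets became 7 at the upper 40%, all 7 among the 11, since fewer probe sets were tested. The count was 0 without moderation, 2114 with array weights that did not converge (1050 higher and 1064 lower), 46 with gene by gene weights (added), both giving WT replicate 3 the largest weight, 2 without WT replicates 1 and 2 (added), and 2 to 12 when each array was left out. The 6 called lists became 0 with an estimated correlation, 0 with fry, 3 with the mean of all probe sets of a gene, 2 with array weights, 2 with gene by gene weights, 2 without WT replicates 1 and 2, and 2 to 6 when each array was left out. In the WT replicates 1 and 2 alternative the elongating spermatid list reversed to −0.011. The 1 called chromosome, X, became 0 with an estimated correlation and 0 with fry, and was called under the other 18 alternatives. Within 10 Mb of Alkbh1, 0 genes passed, and 7 did at an unadjusted p under 0.01 (added). Where no construction is named, the cause was not tested. With the replicate block 9 probe sets changed, 8 of them among the 11, 5 lists and 1 chromosome were called, and Alkbh1 stood at −3.18 (adjusted p = 0.00248). Deviations of same-numbered arrays correlated at 0.223, −0.024 and 0.096. The highest value was that of WT replicate 2 with KO replicate 3 (0.252). With 3 arrays per group these values cannot show whether the numbers pair the samples. An added offset of 16 and a floor at the 20th percentile were not run because the values were already log2, and robust moderation was not run for lists and chromosomes.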

Other observations

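The tests of the X-linked genes, the Sertoli list and the clustering along chromosomes, the splits for that clustering included, were chosen only after those results were seen. The counts over other splits for probe sets, lists and chromosome sets were planned.

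Transcripts of tRNA modification, an activity reported for several AlkB enzymes, held the members closest to passing among the lists that were not called. Thg1l, which adds the 5′ guanosine of histidine tRNA, differed by 0.46 ± 0.10 and Adat2, a subunit of the tRNA adenosine deaminase, by 0.37 ± 0.09 (limma adjusted p = 0.0672 for both adjusted over the list alone, 0.746 and 0.835 over all probe sets). The mitochondrial tRNA methyltransferase gene Trmt5 stood at −0.47 ± 0.13 (limma adjusted p = 0.863), and the maternally expressed imprinted RNA Meg3 at 0.41 ± 0.13 (limma adjusted p = 0.863). Trmt5 and Meg3 lie on chromosome 12, as does Alkbh1.

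Genes at an unadjusted p under 0.01 crowded into 5 of 268 bins of 10 Mb, with 24 of 190 genes against 164 of 13803 in all, on chromosomes 6 (Ptpro, Grin2b, Eps8), 12 (Plekhd1os, Ltbp2) and 14 (Nid2, Fhit, Ktn1, Lgals3, 4930521O11Rik), and without genes known only by clone names 2 of the 5 stayed crowded, that of chromosome 6 and that of Nid2, while that of chromosome 12 did not. Of the 24 genes 12 were lower in KO (50%), but by bin it was 5 of 6 on chromosome 12, 4 of 4 in the bin of Nid2, 2 of 7 on chromosome 6, 1 of 4 in the bin of Ktn1 and 0 of 3 in that of 4930521O11Rik, so sequence mismatches that weaken probes in KO stay open, for chromosome 12 too. Foreign DNA carried along with the targeted allele may account for the bin of chromosome 12, but this stays open. Genes near Alkbh1 were enriched (Fisher's exact p = 0.000368, and 0.166 at the lowest in the other splits of the arrays). That test largely restates the crowding of the bin, since it counts mostly the same genes at a threshold chosen afterwards. No genotypes were used here. Splits that mix KO and WT arrays gave crowded bins in 3 of 9 cases (2, 2 and 5 bins, 9 in all, and 0 in the other 6 splits). Shuffles of the genes' places gave a mean of 0.132 bins over 1000 runs (permutation p = 0.001, the smallest they can give). None of these bins was among the 5, so the mixed splits show such runs at other places only. Whether inherited segments that differ between single animals account for the runs on chromosomes 6 and 14 stays open. In 3 of the 10 splits, the real one included, the most crowded bin was as extreme (−log10 p of 6.92 for KO against WT and 8.87 for the highest other), and 10 splits are too few for a share under 0.05.

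X-linked genes were lower in KO. All 3 KO arrays lay outside the WT range of the X minus autosome value and inside the WT range of the spiked control RNAs. Both were known beforehand, so this count cannot decide on labelling differences. WT replicates 1 and 2 hold the extremes of the spikes (6.69 and 9.41), yet their X minus autosome values were −0.679 and −0.700. WT replicate 3, with spikes at 7.96, stood at −0.670. KO replicates 1, 2 and 3, with spikes at 7.74, 7.59 and 8.10, stood at −0.727, −0.758 and −0.729. These values argue against labelling differences as measured by the spikes, and other technical differences were not tested. The 12 measured sex chromosome genes of the spermatid list differed by −0.13 log2 relative to 72 autosomal spermatid genes, with no overlap between KO and WT arrays, but the sign of this difference followed from lists already seen and only 9 of the 426 X-linked genes enter it, so fewer cells other than spermatids stay open as a cause. A link between loss of Alkbh1 and the X chromosome stays a hypothesis, and a difference between single animals stays open. In 3 of the 10 splits at least as many chromosome sets were called (1 for KO against WT and 1 for the highest other), too few splits for a share under 0.05.

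Sertoli cell genes were lower in KO. All 3 KO arrays lay below the WT range of the Sertoli list and inside the WT range of the spiked control RNAs. This was likewise known beforehand, so the count cannot decide on labelling differences. At the spike extremes, WT replicates 1 and 2 had list means of 0.019 and 0.046, and WT replicate 3 between them had 0.032. KO replicates 1, 2 and 3, with spikes between 7.59 and 8.10, had −0.0041, −0.049 and −0.043. These values argue against labelling differences as measured by the spikes. Fewer somatic cells of every type could also lower the list, and the mean of the Leydig, peritubular, endothelial and macrophage lists differed by −0.0067 log2 against −0.0644 for the Sertoli list, less than that explanation needs, while the difference between them (−0.058) overlapped between KO and WT arrays and was −0.019 without WT replicate 2 (−0.038 against −0.058), which keeps it open. A change in Sertoli cells without Alkbh1 stays a hypothesis.

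In 2 of the 10 splits of the arrays at least as many lists were called (6 for KO against WT and 9 for the highest other). For changed probe sets it was 1 of the 10, with 11 for KO against WT and 2 for the highest other. Both have too few splits for a share under 0.05. The split of WT replicate 1 with KO replicates 1 and 2 against the rest gave 3809 probe sets at an unadjusted p under 0.05. For KO against WT it was 1380. These 3 arrays lay below 0 on the first principal component, and the rest lay above. Their spiked control RNAs read 6.69 to 7.74, against 7.96 to 9.41 in the rest. Their 5′ probe set for 18S ribosomal RNA read 6.63 to 7.65, against 8.35 to 12.16. The split thus followed these technical readings, and whether they caused the differences was not tested.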
